A study of Mus musculus with 8 samples.

How the data were processed

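Gene counts were the deposited values: the authors gave raw counts per gene for 8 libraries, each from the pooled liver RNA of 2 mice at 16 weeks of age. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to mm10 and counted with featureCounts 1.5.0-p3. The annotation release, the strand setting of the counting and the handling of reads shared between genes are not given in the sources used here, so values of paralogs and of genes that overlap on opposite strands are less certain. The table holds 54532 genes and 3 lines without a gene, 1 of which equals the column sums; these lines were left out. Total counts per library lay between 28048469 and 43383157. The most abundant gene, Alb, took between 5.4 and 9.14% of them, and mitochondrial genes between 4.41 and 5.13%. Intervals were not computed for counts, as the replicate spread was used.

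Libraries were grouped by sex and genotype into 4 groups of 2. All 8 libraries were fitted together with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM normalization, the filterByExpr filter, 1 coefficient per group and quasi-likelihood tests with 4 residual degrees of freedom, a prior of 4.93 degrees of freedom and a common dispersion of 0.0156. The 16613 genes tested held 99.9% of the counts. Contrasts were LKO against floxed in females, in males and as the mean of both sexes, the difference of these effects between the sexes, and females against males in each genotype. Adjusted p is Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Values per gene are CPM with TMM factors, as mean and SD of 2 libraries. The overlap of the sexes was set against the product of both counts over the genes tested, per direction.

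A total of 41 gene lists (881 of 931 listed genes tested) of pathways, cell types and handling-related genes were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 genes tested. Beside this stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way and compares a list with no other genes. The lists, contrasts, tests, alternatives and the rule for named genes were fixed before the data were examined. Under this rule Matr3 is named first. For females, males and the mean, protein-coding genes with a symbol that is not a placeholder were ranked, with an adjusted p under 0.05, a mean of at least 1 CPM and every LKO library on the same side of every floxed library within each sex. The 10 largest rises and 10 largest falls were named, or 5 and 5 for the sex difference and the sex comparisons. Each list adds its first 2 genes and up to 4 with the smallest p, and the neighbours of Matr3 serve as a check of the locus. Genes named outside the rule were chosen after their values were seen, which is not said at each of them. The matrix genes that passed in the mean of both sexes are all named.

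The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 2 libraries, a robust prior, a minimum absolute log2 fold change of 1, only the libraries compared, the replicate number as a block, each library left out in turn, and for lists the estimated correlation and fry. A group left with 1 library in such a fit is assumed to vary like the others. The method was tested on simulated data with 100 genes changed per fold. In the female, male, mean and sex difference contrasts, edgeR recovered 81, 76, 91 and 46% of the 2-fold changes and 97, 100, 100 and 86% of the 4-fold changes, with 23, 19, 13 and 14 false calls. In all 4 simulated contrasts false calls were more than 5% of all calls. A list with a planted 1.5-fold change passed by camera, with an estimated correlation (adjusted p = 0.000944) and by fry (adjusted p = 0.000588), and camera called 2 of the 38 lists with no planted change. The simulated genes varied independently of each other, so these list results do not carry over to lists of correlated genes. Figures use the same values, with bars as group means.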

Results

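Liver RNA of 16-week-old chow-fed mice was sequenced as stranded poly(A) libraries. The mice carried floxed Matr3 alleles alone (floxed) or together with Albumin-Cre, which is expressed in the liver (LKO, liver-specific knockout). Matr3 encodes matrin-3, a DNA- and RNA-binding protein of the nuclear matrix. Females and males of both genotypes made 4 groups of 2 libraries each. No group carried Albumin-Cre without floxed Matr3, so effects of Cre itself cannot be told apart from those of Matr3 loss. Below, Matr3 loss stands for LKO against floxed livers. Every library came from RNA of 2 mice, so all p-values measure the spread between pooled libraries. Total counts were 37500913 and 40828005 in the female floxed libraries 1 and 2 and 43383157 and 30493471 in the female LKO libraries. They were 33675732 and 31757189 in the male floxed libraries and 28048469 and 28103290 in the male LKO libraries. Between 21748 and 23194 genes were detected per library. Xist lay between 435.9 and 534.2 CPM (counts normalised to library size) in the female libraries and between 0.036 and 0.448 CPM in the male libraries, and the Y-linked Ddx3y between 45.3 and 58.4 CPM in males and at 0.023 CPM or less in females. The first principal component (55.5% of the variance) followed sex. On the second (12.9%) the floxed libraries lay between 12.7 and 36.8 and the LKO libraries between -17.9 and -23.9. The third (8.5%) set the male floxed libraries 1 and 2 apart (30.1 and -34.7), and this pair differed most among the replicates, with a chi-square per degree of freedom of 58.5 against 12.2, 25.9 and 22.3 in the other groups.

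Matr3 (ENSMUSG00000037236, mm10 chromosome 18, 35562146 to 35593835, plus strand) was measured first, as the deleted gene. Its level was 59.3 and 56.5 CPM in the female floxed libraries and 32.9 and 31.5 CPM in the female LKO libraries. In males it was 56.7 and 52.7 CPM in floxed and 26.4 and 28.6 CPM in LKO livers. The group means were 57.9 ± 1.97 and 32.2 ± 0.937 CPM in females and 54.7 ± 2.81 and 27.5 ± 1.58 CPM in males (SD, n = 2). Matr3 fell in both sexes, with log2 fold changes of -0.85 in females (SE 0.08, adjusted p = 0.0052) and -0.99 in males (SE 0.081, adjusted p = 0.00228). The sex difference of the effect was 0.15 on the log2 scale (adjusted p = 0.83). The counts cover the whole gene, and the floxed exon is not given in the sources used here, so reads from exons outside the deletion and from cells other than hepatocytes are included. The neighbouring genes Snhg4 and Paip2 had mean log2 fold changes of 0.08 (adjusted p = 0.865) and 0.06 (adjusted p = 0.566). The female Matr3 call ended without female floxed 1 (log2 fold change -0.81, adjusted p = 0.0976) and without female LKO 2 (-0.82, adjusted p = 0.0546). The male call ended without male LKO 1 (-0.93, adjusted p = 0.0634) and with only the libraries compared (-0.997, adjusted p = 0.0671).

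**Figure D1:**
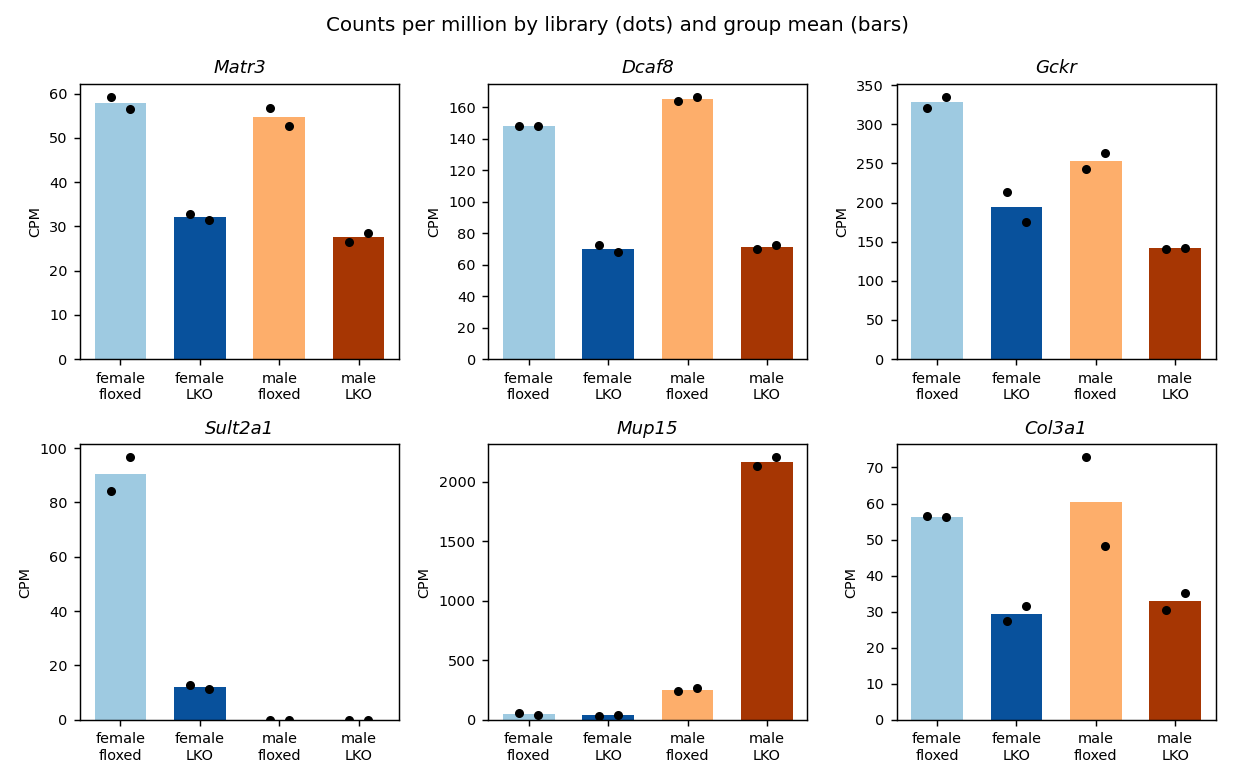
CPM (vertical axes, from 0) of Matr3, Dcaf8, Gckr, Sult2a1, Mup15 and Col3a1 in the 4 groups; bars are group means of 2 libraries and dots are the libraries. Dcaf8 lies at 148.3 and 165.3 CPM in floxed females and males and at 70.2 and 71.3 CPM in LKO, and Mup15 reaches 2171 CPM in LKO males.

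The comparison of LKO with floxed females asked which genes change with Matr3 loss in female liver. Sulfotransferases, which add sulfate to steroids and other small molecules, were among the genes that fell furthest under the naming rule. Sult2a1 (chromosome 7, 13796246 to 13837409) went from 90.4 ± 8.76 to 12.1 ± 1.23 CPM (SD, n = 2), a log2 fold change of -2.90 (SE 0.119, adjusted p = 0.000936). Sult2a2 went from 134.3 ± 6.98 to 24.3 ± 3.79 CPM and Sult5a1 from 23.9 ± 4.15 to 5.63 ± 0.395 CPM, log2 fold changes of -2.46 and -2.08. Pnpla3, a lipase of lipid droplets, fell from 16.8 ± 0.335 to 4.58 ± 1.56 CPM. The others that fell furthest were R3hdml (-3.02), Cyp3a16 (-2.18), Fam129b (-1.26), Gprasp1 (-1.22), Asb3 (-1.22) and the helicase gene Ascc3 (-1.10). Under the same rule, those that rose furthest were AA986860 (2.20), the zinc transporter Slc39a5 (1.84), Serpina7 (1.80), which encodes a thyroxine-binding globulin, the fatty acid hydroxylase Cyp4a14 (1.74), Rad51b (1.71), the major urinary protein gene Mup20 (1.64), the kinase gene Wnk4 (1.57), the chaperone Hspb1 (1.5), Slc35g1 (1.21) and Raet1e (1.19). Gckr, a regulator of glucose metabolism, fell from 328.1 ± 10.3 to 194.2 ± 26.5 CPM (adjusted p = 0.0219). The bile canalicular transporter Abcc2 fell by 0.59 on the log2 scale. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment over 16613 genes, 97 genes passed an adjusted p of 0.05, 45 higher and 52 lower in LKO. The count was 3 without female floxed 1, 17 without female floxed 2, 10 without female LKO 2. It was 396 without male floxed 1, 384 without male floxed 2, 48 without male LKO 1 and 47 without male LKO 2. DESeq2 called 359, limma-voom 154. The fit of the 4 female libraries alone called 343, the fit with no filter 1092 and the robust prior 148, and 39 had an absolute log2 fold change of at least 1. Of the 36 genes named with a female effect that passed, 2, 8, 22 and 7 did so without female floxed 1, female floxed 2, female LKO 1 and female LKO 2. It was 23 without male LKO 1 or male LKO 2. Dcaf8 and Sult2a1 passed without each library, and how reads shared between Sult, Cyp or Mup paralogs were counted is not given in the sources used here. Neither is the strand setting, so the value of R3hdml, which overlaps the antisense gene Hnf4aos, is uncertain.

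Of the 41 gene lists, 15 differed from the other genes in LKO females by camera, 6 higher and 9 lower, and 7 of them passed without each library in turn. Genes of the extracellular matrix and fibrogenesis were lower (31 tested, median -0.49, camera adjusted p = 1.08e-12). The TGF-beta receptor Tgfbr2 (-0.71) and the basement membrane collagen Col4a2 (-0.74) fell over all genes, and 11 fell and 1 rose adjusted over the list alone. The matrix list had an adjusted p of 0.591 with an estimated correlation. Stellate cell and mesenchymal markers, which share Col1a1, Col3a1 and other genes with the matrix list, were lower too (19 tested, median -0.22, adjusted p = 1.57e-05, adjusted p = 0.591 with an estimated correlation). None of them passed over all genes with edgeR, where 7 were lower at an unadjusted p under 0.05 (2342 of 16613 over all genes tested, in either direction). DESeq2 called 3 lower, limma-voom 1, and 3 fell adjusted over the list alone. Cholesterol synthesis genes had a median of -0.36 (26 tested, adjusted p = 1.49e-09, adjusted p = 0.674 with an estimated correlation). With edgeR 0 of them passed over all genes, 15 were lower at an unadjusted p under 0.05, 11 fell adjusted over the list alone. DESeq2 called 7 lower and limma-voom 1. Lipogenesis genes had a median of -0.37 (30 tested, adjusted p = 2.19e-06, adjusted p = 0.591 with an estimated correlation). Pnpla3 fell over all genes and 7 fell adjusted over the list alone. Heat shock genes had a median of 0.40 (13 tested, adjusted p = 2.52e-08, adjusted p = 0.591 with an estimated correlation). Hspb1 rose over all genes and 9 rose adjusted over the list alone. Among female-biased liver genes (33 tested, median -0.15, adjusted p = 3.69e-10, adjusted p = 0.252 with an estimated correlation), Cyp3a16, Sult2a1 and Sult2a2 fell and Cyp4a14 rose over all genes, and 7 fell and 1 rose adjusted over the list alone. The Sult2a2 and Cyp3a16 calls ended with DESeq2, which called 1 gene of this list higher and 1 lower. By limma-voom 1 was higher and 7 were lower. Among male-biased liver genes (35 tested, median 0.12, adjusted p = 0.0127, adjusted p = 0.749 with an estimated correlation), the proteoglycan gene Cspg5 (3.74), Mup20 and Mup21 (1.16) rose over all genes, and 7 rose and 3 fell adjusted over the list alone. Cspg5 rose further than the genes ranked by the naming rule in females, but did not meet its conditions on CPM or on the side of each library. The call of the male-biased list ended with limma-voom (adjusted p = 0.108) and with only the libraries compared (adjusted p = 0.0748).

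The other 8 female list calls each ended without at least 1 library. PPARA targets and fatty acid oxidation genes (40 tested, median 0.16, adjusted p = 0.00101, 0.588 without female LKO 2, adjusted p = 0.749 with an estimated correlation) held 1 gene that rose over all genes, Cyp4a14, and 2 adjusted over the list alone. Glucose metabolism genes (32 tested, median 0.03, mean 0.24, adjusted p = 0.045, 0.265 without female floxed 1 and 0.493 without female LKO 1, adjusted p = 0.749 with an estimated correlation) had 1 gene that rose and 1, Gckr, that fell over all genes, with 7 higher and 1 lower adjusted over the list alone. The glucose call also ended with limma-voom (adjusted p = 0.149) and with the filter of at least 1 CPM in at least 2 libraries (adjusted p = 0.0711). RNA-binding partners of MATR3 and paraspeckle genes (30 tested, median -0.06, adjusted p = 0.0228, 0.0704 without female floxed 1 and 0.225 without female LKO 1, adjusted p = 0.591 with an estimated correlation) had 2 genes that fell over all genes, among them Pspc1 (-0.86), and 3 that fell adjusted over the list alone. Bile duct cell markers (16 tested, median -0.25, adjusted p = 0.0127, 0.0615 without female LKO 1, adjusted p = 0.591 with an estimated correlation) had 2 genes lower adjusted over the list alone. Endothelial markers had a median of -0.17 (23 tested, adjusted p = 0.016, 0.136 without female floxed 2 and 0.656 without female LKO 1, adjusted p = 0.749 with an estimated correlation), and 0 passed adjusted over the list alone. Lipid droplet, uptake and lipolysis genes had a median of 0.13 (31 tested, adjusted p = 0.0279, adjusted p = 0.591 with an estimated correlation), with 4 higher and 1 lower adjusted over the list alone. The droplet list had an adjusted p of 0.0704 without female floxed 1, 0.305 without female LKO 2, 0.0625 without male floxed 1, 0.0655 without male floxed 2 and 0.0615 with limma-voom. The amino acid and urea list (36 tested, median 0.17, adjusted p = 0.0125) and the interferon list (30 tested, median -0.12, adjusted p = 0.0127) each had an adjusted p of 0.749 with an estimated correlation, and 0 genes passed adjusted over the list alone in either. Without female floxed 1 and female LKO 1 the amino acid list had 0.266 and 0.666, and the interferon list 0.198 and 0.243. Over all genes edgeR called 0 of the bile duct, endothelial, droplet, amino acid and interferon genes, with 5, 2, 7, 8 and 5 at an unadjusted p under 0.05. DESeq2 called 1, 0, 5, 2 and 0, and limma-voom 0 in each. The endothelial count at an unadjusted p was not above the share over all genes tested (2342 of 16613).

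The comparison of LKO with floxed males asked the same question in male liver. Mup15 (ENSMUSG00000096674, chromosome 4, 61435790 to 61439743), a member of the major urinary protein cluster, rose from 253.1 ± 16.9 to 2171 ± 47.8 CPM (SD, n = 2), a log2 fold change of 3.10 (SE 0.207, adjusted p = 0.00069). The drug-metabolising enzyme Cyp3a11 rose from 811.1 ± 19.6 to 1341 ± 86.1 CPM, and the AP-1 subunit Jun from 16.6 ± 1.46 to 50.4 ± 15.8 CPM. Under the naming rule, the others that rose furthest were Moxd1 (2.76), Dct (1.29), the retinol dehydrogenase Rdh16 (1.00), Ccdc152 (1.00), the TFIID subunit gene Taf4 (0.61) and Zfp655 (0.51). Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, fell from 18.8 ± 0.718 to 8.52 ± 1.19 CPM. Falls were also seen for Xlr4a (-3.59), Dsg1c (-2.96), Gprasp1 (-1.32), Ascc3 (-1.30), Dcaf8 (-1.21), Naa25 (-1.20), Lrit2 (-1.14) and Cyp2j9 (-1.01). By the same test 34 genes passed, 12 higher and 22 lower in LKO. The count was 11 without female floxed 1 or female floxed 2, 518 without male floxed 2, 7 without male LKO 1 and 13 without male LKO 2. DESeq2 called 252, the fit of the 4 male libraries alone 4, the fit with no filter 873 and the robust prior 55. Of the 25 genes named with a male effect that passed, 6 did so without female floxed 1 or female floxed 2, 16 without female LKO 1, 17 without female LKO 2, 15 without male floxed 1, 3 without male LKO 1 and 5 without male LKO 2. Dcaf8 and Mup15 passed without each library, and reads of Mup and Cyp paralogs are open to the limit named for females.

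By camera 16 lists differed from the other genes in LKO males, 9 higher and 7 lower, and 5 of them passed without each library in turn. Pericentral hepatocyte markers, expressed around the central vein, were higher (20 tested, median 0.51, adjusted p = 3.89e-15, adjusted p = 0.393 with an estimated correlation). Periportal hepatocyte markers did not pass (20 tested, median -0.22, adjusted p = 0.0622). With edgeR 0 of the pericentral genes passed over all genes. At an unadjusted p under 0.05, 14 were higher (1967 of 16613 over all genes tested, in either direction). Adjusted over the list alone, 14 pericentral genes rose. DESeq2 called 7 of them higher and limma-voom 1. Immediate early genes, which respond within minutes and follow tissue handling, were higher as well (19 tested, median 0.89, adjusted p = 9.72e-09, adjusted p = 0.393 with an estimated correlation). Jun rose over all genes, 9 rose and 1 fell adjusted over the list alone, and Fos was at 1.87 ± 0.378 CPM in floxed and 19.97 ± 16.5 CPM in LKO males. Matrix and fibrogenesis genes were lower (31 tested, median -0.44, adjusted p = 3.34e-11, adjusted p = 0.393 with an estimated correlation). With edgeR 0 passed over all genes, 17 were lower at an unadjusted p under 0.05. Adjusted over the list alone 16 fell and 1 rose, DESeq2 called 5 lower and limma-voom 0. Stellate cell and mesenchymal markers had a median of -0.32 (19 tested, adjusted p = 7.32e-06, adjusted p = 0.427 with an estimated correlation), and T, NK and B cell markers one of -0.41 (23 tested, adjusted p = 0.00041, adjusted p = 0.393 with an estimated correlation). In these, 4 and 2 genes fell adjusted over the list alone. EdgeR called 0 over all genes, with 9 and 7 lower at an unadjusted p under 0.05. By DESeq2 it was 2 and 1, and by limma-voom 0.

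The other 11 male list calls each ended without at least 1 library. PXR targets (12 tested, median 0.47, adjusted p = 0.00122, 0.0806 without male floxed 2, adjusted p = 0.393 with an estimated correlation) held Cyp3a11, which rose over all genes, and 7 higher and 1 lower adjusted over the list alone. PPARA targets had a median of 0.08 and a mean of 0.27 (40 tested, adjusted p = 0.00135, 0.137 without male floxed 2 and 0.0681 without male LKO 1, adjusted p = 0.577 with an estimated correlation). Lipid droplet genes had a median of 0.02 and a mean of 0.21 (31 tested, adjusted p = 0.0102, 0.775 without male floxed 2 and 0.118 without male LKO 1, adjusted p = 0.393 with an estimated correlation). Both lists hold the droplet protein gene Cidea (4.33, adjusted p = 0.0386), the only gene of either to pass over all genes with edgeR. The Cidea call ended with limma-voom, with the replicate number as a block and with only the libraries compared. Cidea rose further than the genes ranked by the naming rule in males, but did not meet its conditions on CPM or on the side of each library. Adjusted over the list alone, 6 PPARA targets were higher and 1 lower, and 6 droplet genes higher and 2 lower. Phase II conjugation genes had a median of 0.18 (40 tested, adjusted p = 0.00041, 0.0962 without male floxed 1, adjusted p = 0.493 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone. CAR targets had a median of 0.12 (24 tested, adjusted p = 0.0189, 0.484 without male floxed 1 and 0.118 without male LKO 1, adjusted p = 0.577 with an estimated correlation), with 4 higher adjusted over the list alone. Male-biased liver genes had a median of 0.06 (35 tested, adjusted p = 0.00796, 0.599 without male floxed 1 and 0.574 without male LKO 2, adjusted p = 0.581 with an estimated correlation). Moxd1 rose over all genes, and 2 rose and 1 fell adjusted over the list alone. Bile duct cell markers had a median of -0.24 (16 tested, adjusted p = 0.0107, 0.255 without male floxed 2 and 0.538 without male LKO 2, adjusted p = 0.427 with an estimated correlation), with 3 lower adjusted over the list alone. The remaining 4 lists had 0 genes adjusted over the list alone. Cholesterol synthesis genes had a median of -0.20 (26 tested, adjusted p = 0.00041, 0.408 without male floxed 1 and 0.0701 without male LKO 1, adjusted p = 0.577 with an estimated correlation). Circadian clock genes had a median of 0.15 (21 tested, adjusted p = 0.0496, 0.218 without male floxed 2 and 0.184 without male LKO 1, adjusted p = 0.577 with an estimated correlation). The clock call also ended with RLE size factors (adjusted p = 0.0509) and the filter of at least 1 CPM in at least 2 libraries (adjusted p = 0.0592). Kupffer cell markers had a median of -0.18 (22 tested, adjusted p = 0.00577, 0.183 without male floxed 1 and 0.936 without male LKO 2, adjusted p = 0.577 with an estimated correlation). The MATR3 partner list had a median of -0.12 (30 tested, adjusted p = 0.012, 0.0605 without male floxed 1, 0.0604 without male floxed 2 and 0.109 without male LKO 1, adjusted p = 0.393 with an estimated correlation). Over all genes edgeR called 0 of the phase II, CAR, bile duct, cholesterol, clock, Kupffer and MATR3 partner genes, with 14, 8, 3, 5, 1, 2 and 6 at an unadjusted p under 0.05. DESeq2 called 4, 2, 1, 0, 1, 1 and 0, and limma-voom 0 in each. The clock and Kupffer counts at an unadjusted p were not above the share over all genes tested (1967 of 16613).

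The overlap of the female and male results asked which genes changed with Matr3 loss in both sexes. The contrasts share no library, but they come from 1 fit and share the dispersion of each gene, so the gene sets called are not independent. Dcaf8 (ENSMUSG00000026554, chromosome 1, 172148084 to 172197005), a substrate receptor of ubiquitin ligases, fell from 148.3 ± 0.228 to 70.2 ± 2.80 CPM in females and from 165.3 ± 1.90 to 71.3 ± 1.58 CPM in males (SD, n = 2), log2 fold changes of -1.08 and -1.21. Ascc3, the NatB acetyltransferase subunit gene Naa25 (-0.83 and -1.20), Gprasp1, Gckr (-0.76 and -0.84) and the vitamin E-binding protein gene Afm (-0.60 and -0.65) fell in both sexes. Srpr (-0.82 and -0.78), part of the signal recognition particle receptor, Oxr1 (-0.79 and -0.59), an oxidation resistance gene, and the protease inhibitor gene Tfpi2 (-0.63 and -0.60) also fell in both, and were chosen after their values were seen. Taf4 (0.71 and 0.61) and Ccdc152 (0.83 and 1.00) rose in both. In all, 18 genes passed in both sexes in the same direction and edgeR called 0 in opposite directions. Independent lists would share 0.0325 higher and 0.0689 lower genes, against 3 and 15; a hypergeometric p-value is not given, as it assumes independence. Of the 97 genes that passed in females, 79 had the same sign in males, and 28 of the 34 male genes had the same sign in females. Across all genes tested the female and male log2 fold changes had a Pearson r of 0.232 and a Spearman rho of 0.265, where genes are not independent replicates. The shared count was 2 without female floxed 1, 3 without female floxed 2, 4 without female LKO 2, 103 without male floxed 2, 4 without male LKO 1 and 6 without male LKO 2. It was 72 with DESeq2, 267 with no filter, 2 with only the libraries compared and 8 at an absolute log2 fold change of at least 1.

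**Figure D2:**
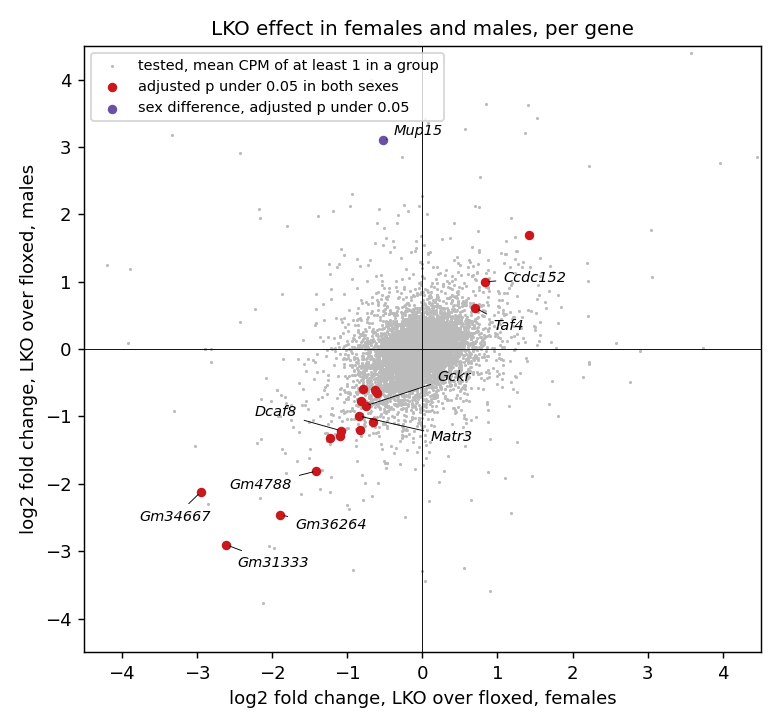
Log2 fold change of LKO over floxed in females (horizontal axis) and males (vertical axis) for 13561 genes with a mean of at least 1 CPM in a group; 9 of them lie beyond the axes, which end at 4.5. Red points passed in both sexes (18 genes), 15 of them at the lower left, and Mup15 (purple) lies at -0.53 in females and 3.10 in males.

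The mean of both within-sex effects asked what changes with Matr3 loss across the sexes, from 4 against 4 libraries. The genes that rose furthest under the naming rule were the nuclear receptor Nr4a1 (2.48), which is also an immediate early gene but absent from the list tested here, Cyp4a14 (1.45), the pantetheinase gene Vnn1 (1.36), AA986860 (1.34), Adgrg2 (1.26), Slc39a5 (1.24), Fitm1 (1.23), which acts in lipid droplet formation, the cohesin gene Rec8 (1.19), Treh (1.18) and Mup20 (1.12). Those that fell furthest were the glutamate receptor gene Grid1 (-2.49), Dsg1c (-2.47), R3hdml (-2.23, uncertain as in females), Gpr12 (-1.69), Fabp5 (-1.67), Foxq1 (-1.67), Col4a5 (-1.55), Fhit (-1.39), Efna3 (-1.29) and Gprasp1 (-1.27). Of the genes that passed in the mean contrast, 285 had the same sign in both sexes. A test of the mean favours such genes, so this is no separate evidence that the sexes agree. By edgeR 291 genes passed, 129 higher and 162 lower in LKO, of which 116 and 149 are protein coding. The count was 33 without female floxed 1, 39 without female floxed 2, 132 without female LKO 1, 87 without female LKO 2, 1114 without male floxed 2, 32 without male LKO 1 and 57 without male LKO 2. DESeq2 called 619 and the fit with no filter 1560, and 71 had an absolute log2 fold change of at least 1. Of the 69 genes named with a mean effect that passed, here and among the other observations, 13, 14, 39 and 29 did so without female floxed 1, female floxed 2, female LKO 1 and female LKO 2. It was 60, 68, 11 and 18 without male floxed 1, male floxed 2, male LKO 1 and male LKO 2. 10 passed without each library, among them Matr3, Gckr, Afm, Gprasp1, Mup21 and Oxr1.

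By camera 17 lists differed from the other genes in the mean of both sexes, 8 higher and 9 lower. In lipid metabolism the cholesterol synthesis and lipogenesis lists were lower, and the PPARA target and lipid droplet lists were higher. Among cholesterol synthesis genes (26 tested, median -0.27, adjusted p = 1.83e-09, adjusted p = 0.466 with an estimated correlation), the sterol enzymes Cyp51 (-0.39), Lss (-0.60) and Nsdhl (-0.42) fell over all genes, and 15 fell adjusted over the list alone. Among lipogenesis genes (30 tested, median -0.18, adjusted p = 0.00182, adjusted p = 0.466 with an estimated correlation), the desaturase gene Scd2 (-0.87) and Pnpla3 (-1.002) fell over all genes, and 7 fell adjusted over the list alone. Among PPARA targets and fatty acid oxidation genes (40 tested, median 0.12, adjusted p = 0.000131, adjusted p = 0.519 with an estimated correlation), Cyp4a14 and Vnn1 rose over all genes, and 9 rose and 2 fell adjusted over the list alone. Among lipid droplet, uptake and lipolysis genes (31 tested, median 0.09, adjusted p = 0.00674, 0.247 without male floxed 2, adjusted p = 0.355 with an estimated correlation), the fatty acid transporter Cd36 (0.77), Fitm1 and the fatty acid-binding protein gene Fabp2 (0.48) rose and Fabp5 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. Among glucose metabolism genes (32 tested, median 0.11, adjusted p = 0.0206, 0.0671 without female floxed 1 and 0.138 without female LKO 1, adjusted p = 0.466 with an estimated correlation), glucose-6-phosphatase (G6pc, 0.77) rose and Gckr (-0.80) fell over all genes, and 2 rose and 1 fell adjusted over the list alone.

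Genes of collagens and other matrix proteins made the list with the lowest camera p in the mean contrast (31 tested, median -0.47, adjusted p = 4.87e-18, adjusted p = 0.355 with an estimated correlation). Over all genes 9 fell, namely Col1a1 (-1.001), Col1a2 (-0.70), Col3a1 (-0.91), Col4a1 (-0.44), Col4a2 (-0.47), Col6a1 (-0.60), the collagen crosslinking enzyme gene Lox (-1.78), Sparc (-0.54) and Timp2 (-0.53), and 21 fell adjusted over the list alone. Lox, the largest of these falls, was too low for the filter of at least 1 CPM in at least 2 libraries. Col3a1 went from 56.3 ± 0.251 to 29.5 ± 3.01 CPM in females and from 60.5 ± 17.3 to 32.9 ± 3.27 CPM in males. Markers of other cell types moved with them. Stellate cell and mesenchymal markers had a median of -0.28 (19 tested, adjusted p = 2.95e-08, adjusted p = 0.355 with an estimated correlation). Lrat (-0.42), which esterifies retinol, fell over all genes with Col1a1 and Col3a1, and 9 fell adjusted over the list alone. Bile duct cell markers had a median of -0.34 (16 tested, adjusted p = 0.00123, adjusted p = 0.355 with an estimated correlation). Bicc1 (-0.81) fell over all genes and 4 fell adjusted over the list alone. T, NK and B cell markers had a median of -0.28 (23 tested, adjusted p = 0.00407, adjusted p = 0.355 with an estimated correlation) and endothelial markers one of -0.11 (23 tested, adjusted p = 0.0109, 0.254 without female LKO 1, 0.273 without male floxed 2 and 0.0907 without male LKO 1, adjusted p = 0.668 with an estimated correlation). In these, 2 and 1 genes fell adjusted over the list alone. EdgeR called 0 over all genes, with 5 and 4 lower at an unadjusted p under 0.05, DESeq2 called 1 in each, and limma-voom 0. The endothelial count at an unadjusted p was not above the share over all genes tested (3021 of 16613). Among cell cycle genes (39 tested, median -0.22, adjusted p = 0.0206, 0.0638 without female floxed 2, 0.0672 without male floxed 1 and 0.107 without male LKO 2, adjusted p = 0.466 with an estimated correlation), the replication helicase gene Mcm5 (-0.93) fell over all genes, and 1 rose and 2 fell adjusted over the list alone. Kupffer cell (adjusted p = 0.399), neutrophil (0.399), red blood cell (0.463) and neighbouring tissue (0.507) markers did not pass.

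Pericentral hepatocyte markers were higher in the mean of both sexes (20 tested, median 0.30, adjusted p = 9.42e-09, adjusted p = 0.384 with an estimated correlation). The glutamate transporter Slc1a2 (0.46) and the ornithine aminotransferase Oat (0.47) rose over all genes, and 10 rose adjusted over the list alone. Among PXR targets (12 tested, median 0.39, adjusted p = 0.00182, adjusted p = 0.355 with an estimated correlation), Cyp3a11 (0.65) and the glutathione transferase Gstm2 (0.42) rose over all genes, and 8 rose and 2 fell adjusted over the list alone. Heat shock genes had a median of 0.28 (13 tested, adjusted p = 2.92e-05, adjusted p = 0.355 with an estimated correlation). Hspb1 (0.92) rose over all genes and 6 rose adjusted over the list alone. Immediate early genes had a median of 0.50 (19 tested, adjusted p = 0.000498, 0.0575 without male floxed 2, adjusted p = 0.466 with an estimated correlation). With edgeR 0 of them passed over all genes, 7 were higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone 7 rose and 1 fell, DESeq2 called 6 higher and 1 lower, and limma-voom 0. Among RNA-binding partners of MATR3 and paraspeckle genes (30 tested, median -0.10, adjusted p = 0.00257, adjusted p = 0.355 with an estimated correlation), 3 genes fell over all genes, among them Pspc1 (-0.61) and the paraspeckle RNA Neat1 (-0.41), and 4 fell adjusted over the list alone. Malat1, another nuclear RNA of the list, had a value close to that of Neat1 (-0.43, adjusted p = 0.119), so less nuclear RNA in the LKO libraries is not excluded as the cause of the Neat1 value. Among male-biased liver genes (35 tested, median 0.13, adjusted p = 0.00225, 0.126 without male LKO 2, adjusted p = 0.576 with an estimated correlation), Mup20, Mup21 (1.03) and Cspg5 (1.88) rose and Serpina1e (-0.69) fell over all genes, and 8 rose and 1 fell adjusted over the list alone. Here too Cspg5 did not meet the naming rule's conditions on CPM or on the side of each library. With an estimated correlation 0 lists passed in the female, male and mean contrasts, while the test of each list on its own (fry) called 0, 1 and 3. The fry calls were the hepatocyte identity list in males (adjusted p = 0.0409) and in the mean (0.0293), and in the mean also the nuclear receptor list (0.0293) and the MATR3 partners (0.0498). Lists that did not pass by camera held single genes that did. Crp (0.64) of the acute phase list (list adjusted p = 0.631) rose. Apoa1 (-0.37) and the transcription factor gene Foxa3 (-0.37) of the hepatocyte identity list (list adjusted p = 0.208 by camera) fell. Among transporter genes of the bile acid list (list adjusted p = 0.264), Abcc2 (-0.49) fell and Abcg5 (0.38) rose.

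**Figure D3:**
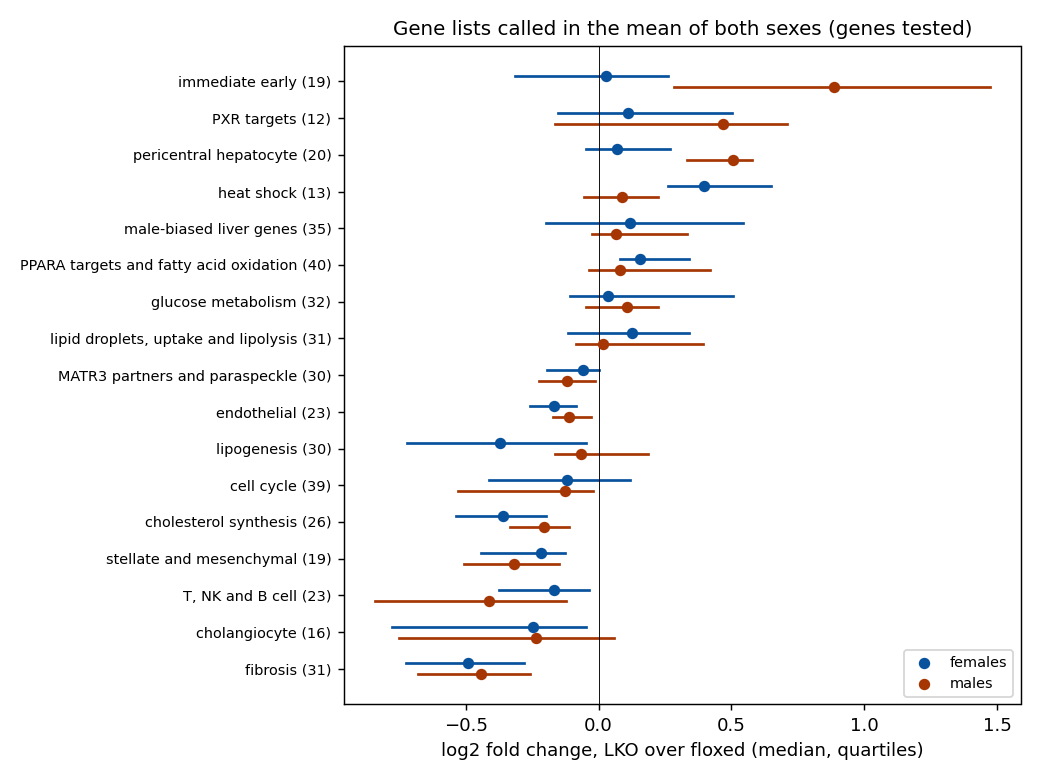
Median log2 fold change of LKO over floxed (horizontal axis; bars span the quartiles of the genes) in females (blue) and males (brown-red) for the 17 lists that passed by camera in the mean of both sexes, with the number of genes tested in brackets. The matrix list lies at -0.49 in females and -0.44 in males, and the pericentral list at 0.51 in males.

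The sex difference of the effect asked where LKO changed a gene more in one sex than in the other. Mup15 alone passed by edgeR, with a difference, female effect minus male effect, of -3.63 on the log2 scale (adjusted p = 0.00734). It was at 52.3 ± 11.8 and 36.4 ± 10.2 CPM in floxed and LKO females (SD, n = 2; adjusted p = 0.275) and rose in males. Other genes that passed in one sex only did not pass for the difference by edgeR, as with Jun (difference -2.00, adjusted p = 0.149), Hspb1 (1.17, adjusted p = 0.45) and Pnpla3 (-1.72, adjusted p = 0.41). These 3 did pass with DESeq2 (adjusted p = 0.00891 or lower) and with no filter, so a sex difference of them stays open. At an unadjusted p under 0.05 there were 1189 genes, and DESeq2 called 78. The Mup15 call ended without male LKO 1 or male LKO 2, where edgeR called 0 genes. The count was 5 without female LKO 1, 2 without male floxed 1, 96 without male floxed 2, 439 with no filter and 11 with the robust prior.

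By camera 8 lists differed between the sexes in their LKO effect. The median difference was positive (higher in the female contrast) for heat shock (0.30), periportal hepatocyte (0.25), Kupffer cell (0.21) and amino acid and urea genes (0.16). It was negative for immediate early (-0.78), pericentral hepatocyte (-0.34), lipogenesis (-0.32) and phase II conjugation genes (-0.13). Each had an adjusted p between 0.935 and 0.975 with an estimated correlation, and edgeR called 0 of their genes over all genes. At an unadjusted p under 0.05, in the order named, 5, 4, 3 and 4 were higher, and 6, 5, 5 and 8 lower. DESeq2 called 1, 0, 1 and 1 higher and 2, 1, 1 and 4 lower, and limma-voom 0. Adjusted over the list alone, 1, 0, 1 and 1 were higher and 5, 1, 1 and 7 lower. The count of lists was 13 without female floxed 1 or female LKO 2 and 14 without male floxed 2. The heat shock and lipogenesis lists passed without each library. The others ended, for the periportal list without male floxed 1 (adjusted p = 0.491), for the Kupffer list without male floxed 1 (0.0763) or male LKO 2 (0.321), and for the immediate early list without male LKO 1 (0.0594). So they did for the pericentral list without male floxed 1 (0.0763), for the phase II list without male floxed 1 (0.18), and for the amino acid list without female floxed 1 (0.342), female LKO 1 (0.764), male floxed 1 (0.527) or male LKO 1 (0.124).

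The comparison of females with males within each genotype asked whether the sex bias of liver genes was present with and without Matr3. Female-biased genes stood higher in females in both genotypes. Cux2, a transcription factor gene of female liver, was at 67.2 ± 2.23 CPM in floxed females and 0.739 ± 0.187 CPM in floxed males, and at 76.6 ± 9.27 and 0.546 ± 0.107 CPM in LKO females and males (SD, n = 2). Cyp2b9 was at 408.6 and 0.32 CPM in floxed and 282.2 and 0.11 CPM in LKO females and males. The steroid dehydrogenase Hsd3b5 was at 4.46 and 266.5 CPM in floxed and 3.38 and 269 CPM in LKO females and males. Cux2 and Hsd3b5 were named outside the rule. Of 33 female-biased genes 31 were higher in females in either genotype over all genes and 32 in either adjusted over the list alone (adjusted p = 0.000149 in floxed and 0.000189 in LKO with an estimated correlation). Of 35 male-biased genes 35 were lower in females in floxed livers and 34 in LKO livers over all genes, and 35 in either adjusted over the list alone (adjusted p = 0.0145 and 0.0199 with an estimated correlation). Both lists were written from known sex bias. By camera 15 lists passed in floxed and 14 in LKO livers, and 3 in each with an estimated correlation. The growth hormone and IGF axis, which sets sex bias in liver and shares Cux2 with the female-biased list, had 5 genes higher and 1 lower of 17 tested in either genotype over all genes, 8 higher and 1 lower in floxed and 6 higher and 2 lower in LKO adjusted over the list alone (adjusted p = 0.031 and 0.0446 with an estimated correlation). By edgeR 1081 genes differed between the sexes in floxed livers (537 higher and 544 lower in females) and 1411 in LKO livers (655 higher and 756 lower). The floxed count was 346 without female floxed 1, 361 without female floxed 2, 704 with only the libraries compared, 2098 with no filter and 518 at an absolute log2 fold change of at least 1. The LKO count was 823 without female LKO 1, 602 without female LKO 2, 662 without male LKO 1, 533 without male LKO 2, 2514 with no filter and 583 at that minimum.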

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

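Tests of Mup read sharing and of a strain variant were chosen only after the Mup15 result was seen; the tests of the sex difference were planned. The results here stand apart because the effect of LKO differed between females and males when that difference itself was tested. Mup15 differed by -3.63 on the log2 scale, female effect minus male effect (adjusted p = 0.00734), with both LKO male libraries above both floxed male libraries, and the call ended without male LKO 1 or male LKO 2 (0 genes). For lists, the median difference was -0.34 for pericentral hepatocyte genes (adjusted p = 2.58e-06), -0.78 for immediate early genes (5.61e-06), 0.30 for heat shock genes (0.000215), -0.32 for lipogenesis genes (0.000215), -0.13 for phase II conjugation genes (0.000498), 0.21 for Kupffer cell markers (0.000498), 0.25 for periportal hepatocyte genes (0.00154) and 0.16 for amino acid and urea genes (0.0394). With an estimated correlation 0 of these 8 list calls passed, at adjusted p values between 0.935 and 0.975, and 6 calls ended without single libraries. Without male floxed 1 the adjusted p was 0.0763 for pericentral, 0.18 for phase II, 0.491 for periportal, 0.0763 for Kupffer and 0.527 for amino acid genes. It was 0.321 for Kupffer markers without male LKO 2, 0.0594 for immediate early and 0.124 for amino acid genes without male LKO 1, and 0.342 and 0.764 for amino acid genes without female floxed 1 and female LKO 1.

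Mup15 was at 241.1 and 265 CPM in floxed males and at 2137 and 2205 CPM in LKO males, against 60.7 and 43.9 CPM in floxed and 29.2 and 43.6 CPM in LKO females. Reads passed between Mup paralogs are not excluded as a cause of the Mup15 rise. The Mup15 share of all Mup counts was 1.34 and 0.746% in floxed males and 5.02 and 4.36% in LKO males. The lowest LKO share was 3.26 times the highest floxed share. The sum of the other 33 Mup genes was 17785 and 35281 CPM in floxed and 40481 and 48372 CPM in LKO males. As this sum was not lower, the values argue against reads merely moved to Mup15 within an unchanged Mup total. Only the sum was compared. A rise of a single paralog with reads counted as Mup15 could give the same values. A strain variant in the Mup cluster stays open, since the female value of -0.53 (adjusted p = 0.275) excludes no variant that acts under male hormone levels. An effect of Matr3 loss that needs a male liver may also account for it, and was not tested apart from the comparison itself.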

How the results depend on the processing

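The crossed replicate block was the alternative chosen after seeing the data; all others were planned. Counts of calls that moved beyond 1.5 times are given with the setting, and the cause was not tested. With DESeq2, 359 genes passed in females, 252 in males, 619 in the mean, 78 in the sex difference and 72 in both sexes, and with limma-voom 154 in females. With no filter the counts were 1092, 873, 1560, 439 and 267, and 2098 and 2514 in the floxed and LKO sex comparisons. The robust prior gave 148 in females, 55 in males and 11 in the sex difference. Only the libraries compared gave 343 in females, 4 in males, 704 in the floxed sex comparison and 2 in both sexes, and no value for the mean and the sex difference, which need all 8. At an absolute log2 fold change of at least 1 the counts were 39 in females, 71 in the mean, 518 and 583 in the sex comparisons and 8 in both sexes. With an estimated correlation 0 lists passed in the female, male, mean and sex difference contrasts, and with fry 0, 1, 3 and 0. Leaving out each library in turn, the counts ranged from 3 to 396 in females, 7 to 518 in males, 32 to 1114 in the mean, 0 to 96 in the sex difference, 346 to 1466 and 533 to 2085 in the floxed and LKO sex comparisons and 2 to 103 in both sexes. The lists ranged from 10 to 17 in females, 14 to 19 in males, 16 to 23 in the mean and 6 to 14 in the sex difference. In all, 112 of 185 such values stayed within 1.5 times. With the replicate number as a block, 84, 29, 236, 1, 1020 and 1334 genes passed in the 6 contrasts, 16 in both sexes, and 15, 16, 18 and 10 lists. This block kept 74 of the 97 female, 25 of the 34 male and 218 of the 291 mean calls. Of 147 results of named genes, 23 lost the call with it. Same-numbered libraries did not deviate together over all genes (correlations between -0.102 and 0.0573). Whether the numbers mark a batch that acts on some genes is not known from these values or from the labels. As the female floxed and LKO libraries had -0.102, the pairing was also crossed, which gave 78, 11, 223, 1, 992 and 1311 genes. All 97 female, 34 male and 291 mean calls kept their sign under the alternatives that tested them (280 of the 291 with the stricter filter). Among named genes, the sign turned only for values that did not pass, Snhg4 (-0.014 to 0.199 leaving out each library) and Psmb8 (-0.032 to 0.127). Genes too low for the filter, all but 16613, were not tested, and in simulated data 2-fold changes were recovered less often than 4-fold ones.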

Other observations

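The tests of GC content and exonic length, RNA degradation, nuclear RNA, cell type shares and portal tissue were chosen only after the results were seen, as were the loci in the next sentences; the counts of other splits were planned. Of 7 class I histocompatibility genes looked at on chromosome 17, 4 fell in LKO livers in the mean of both sexes, namely H2-T23 (-0.55, adjusted p = 0.0164), H2-Q7 (-0.54, adjusted p = 0.0173), H2-Q6 (-0.50, adjusted p = 0.0286) and H2-K1 (-0.32, adjusted p = 0.0473). H2-D1 (-0.17), H2-Q4 (-0.27, adjusted p = 0.116), H2-Q10 (-0.05, adjusted p = 0.71), the light chain gene B2m (-0.21), the peptide transporter gene Tap1 (-0.04) and the immunoproteasome genes Psmb8 (0.05) and Psmb9 (0.15) did not pass. The H2 genes are close paralogs, so their separate values are uncertain. On chromosome 2 the antisense gene Hnf4aos (-1.74, adjusted p = 0.0169), which overlaps Hnf4a, and R3hdml (-2.23), which lies beside Hnf4a, fell. Hnf4a had a value of 0.10 (adjusted p = 0.417). As the strand setting of the counting is not given in the sources used here, the values of Hnf4aos, and of R3hdml and Hnf4a, which overlap it, are uncertain. The falls of Hnf4aos and R3hdml do not count as separate results. The noncoding genes Gm34667 (-2.53) and Gm31333 (-2.76) on chromosome 12 and Gm36264 (-2.18) on chromosome 13, and the pseudogene Gm8893 (-0.87) on chromosome 12, fell in both sexes. In the mean contrast these 4 noncoding loci passed without each library in turn, while the count of genes called in both sexes fell to 2 without female floxed 1. Each of the 4 H2 genes that passed, Hnf4aos and R3hdml lost its call without female floxed 1, female floxed 2, male LKO 1 or male LKO 2, and H2-Q6, H2-K1 and Hnf4aos also without female LKO 2 and H2-K1 without female LKO 1. Their log2 fold changes then stayed below 0, from -0.60 to -0.50 for H2-T23, -0.60 to -0.48 for H2-Q7, -0.60 to -0.42 for H2-Q6, -0.36 to -0.28 for H2-K1, -1.93 to -1.46 for Hnf4aos and -2.44 to -1.93 for R3hdml over all alternatives run. H2-K1 also lost its call with the replicate number as a block.

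Of the 35 splits of the 8 libraries into 4 and 4, 2 called as many genes as the real split of the mean contrast (291). These were the real split and the split by sex, which called 1917 and points to sex as a structure of the samples. With the sex split among the 35, this share could not fall under the threshold and does not decide on chance. Without the sex split the highest other count was 28. Among the 18 splits with both sexes evenly on each side, 1 reached 291, the real one, and the highest other called 3. The real split always counts among the 18, so that share could not fall under the threshold either. Every other balanced split has both genotypes on each side, and so is no grouping free of a genotype effect. For gene lists, 10 of the 35 splits called as many as the real split (17), the highest other called 23, and 6 of the 18 balanced splits reached 17, so chance is not excluded for the number of lists.

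Long genes were lower in LKO livers: of 192 protein-coding genes that span over 400 kb, 14 fell in the mean contrast, among them Fhit (-1.39), Grid1 (-2.49), Wwox (-0.64) and Oxr1 (-0.69), and their median was -0.23, against 0.02 for genes under 10 kb, while over expressed genes alone it was -0.08 (89 genes, 10 lower) against 0.04 (of the genes named, Oxr1 passed without each library, and the others lost the call without female floxed 2, male LKO 1 or male LKO 2, among others). With GC content, exonic length and expression in the regression, the slope on span differed by -0.073 between LKO and floxed libraries over all protein-coding genes (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 libraries can give; -0.07 uncorrected), and by -0.053 over expressed genes (exact p = 0.0571; -0.048 uncorrected, exact p = 0.171); the correction shrank the difference in neither set, which argues against GC content and exonic length, but they are not excluded, as the value over expressed genes misses the threshold, and the gene set, the bounds and the centring over all 8 libraries were chosen after results were seen, and centring within each sex gave 0.0286 in both sets. All these exact p values, also those centred within each sex, come from permutations that swap libraries between the sexes. With swaps kept within each sex, the smallest possible exact p would lie above 0.05, so 0.0286 does not decide whether the slopes differ. RNA degradation would lower genes with long exons. The exonic slope differed by 0.032 (exact p = 0.4), which does not decide on degradation. Less nuclear RNA in the LKO libraries stays open too, as Neat1 (-0.41) and Malat1 (-0.43, adjusted p = 0.119) were lower in the mean contrast. The other nuclear-retained RNAs had medians of -0.13 in females (6 RNAs) and -0.14 in males (5 RNAs). Of these Nlrp6 alone passed in the mean contrast (-0.55, adjusted p = 0.024). Airn (-0.14, under 1 CPM), Mlxipl (-0.12), Kcnq1ot1 (-0.004), Gcgr (0.05) and Xist (-0.21 in females) did not. A role of matrin-3 in transcribing or processing long genes is a candidate explanation that may be followed up and was not tested apart from these values.

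Matrix genes were lower in LKO livers, with a mean score difference of -0.454 (LKO minus floxed, exact permutation p = 0.0286, 0.154 after adjustment over 9 scores) and 4 of 4 LKO libraries below all floxed ones. The exact p values of the scores also come from swaps between the sexes and carry the limit named for the span slopes. A lower share of all non-hepatocyte cells stays open: the matrix score fell further than that of endothelial and Kupffer cell markers by a difference of -0.331 (exact p = 0.0857), which misses the threshold. Matrix minus endothelial and Kupffer score was 0.119 and 0.03 in floxed and -0.3 and -0.386 in LKO females. In males it was 0.507 and 0.006 in floxed and -0.026 and 0.05 in LKO libraries, so the male part rests on male floxed 1. Less portal tissue in the LKO samples may also account for the pattern, since the bile duct cell score differed by -0.365 (exact p = 0.0571) and the matrix score, set against it, by only -0.088 (exact p = 0.771). Scores centred within each sex, the first choice, gave exact p values of 0.0571, 0.0286 and 0.6 for these 3, and centring over all 8 libraries was chosen after results were seen, as were the bounds of the first of these tests. An effect of hepatocyte Matr3 loss on matrix-producing cells is the biological alternative and cannot be told apart from these explanations here.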
